A study of Canis lupus familiaris with 12 samples.

How the data were processed

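RNA of MDCK cells, a dog kidney epithelial line, transfected with Snail, Slug or E47 was hybridised against RNA of MDCK-CMV control cells on 2-colour cDNA arrays with probes for cancer-related human genes. Per the labels, each transfectant has samples numbered 1 and 2, and each sample was hybridised with the transfectant in Cy5 and again with the transfectant in Cy3, which gives 4 arrays per transfectant and 12 in all. No array compared control with control.

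The deposited table holds, for 13056 probes on each array, a log2 ratio of the 2 channels, with empty cells where a value is missing. That the deposited values are log2 was checked on the numbers: on every array, 100.00% of the antilogs of values below -0.5 fell on whole thousandths within 0.00006 on the log2 scale, where values spread evenly would give 4.41% to 5.07%. Array medians lay between -0.0634 and 0.0594, so the deposited ratios were centred; the method, the scanner, the background correction and the filter behind empty cells are not given in the sources used here. Values were present for 10654 probes (sample Snail 2, titled Cy5) to 12982 probes (Slug 1, titled Cy5), and for 8289 probes on all 12 arrays. Signal over background is not part of these values, and the number of arrays limits the precision.

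Probe names came from the table that pairs the probe IDs with gene symbols and Entrez IDs: 8047 probes had 1 symbol, 276 had several and 4733 had none. Only probes with 1 symbol entered the gene values, which gave 4325 genes, 527 of them with several clones. Spots of a clone were averaged first and clones of a gene next; ACTN1 alone has 50 spots of 1 clone. No probe is named SNAI2, the gene of Slug, so its level is not analysed here.

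The labels name the dye of the transfectant on each array but not which channel is the numerator of the ratio, and the signs of the values did not follow the dyes. Both arrays of Snail 1, Slug 2 and E47 1 and the E47 2 array titled Cy3 ran one way, and both arrays of Snail 2 and Slug 1 and the E47 2 array titled Cy5 ran the other way. Within each transfectant the 4 arrays were therefore turned to a common sign by the leading eigenvector of their correlation matrix, computed without the CDH1 probes. The sign of the transfectant was then set so that the mean of the CDH1 probes lay below 0, since Snail, Slug and E47 are known as repressors of CDH1. After this, 7 arrays kept their sign and 5 were turned. This choice was made after the values were seen, and the labels do not settle it: directions against the control are called assumed, and a fall of CDH1 is no finding. Whether 2 genes moved to the same side or to opposite sides within a transfectant does not depend on the sign set by CDH1. It does rest on the turning of the 4 arrays to a common sign. The design planned before the data were examined took dye to be balanced within each numbered sample; by the apparent orientations this holds over the 4 arrays of Snail and of Slug, 2 in each orientation, but not within their numbered samples, and E47 has 3 arrays in one orientation and 1 in the other.

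Turned log2 ratios of the 2 arrays of a numbered sample were averaged to 1 replicate value, for which both arrays were needed, giving 2 replicates per transfectant. limma 3.58.1 in R 4.3.3 fitted all 3 groups together without an intercept, with 3 residual degrees of freedom for a complete gene and empirical Bayes moderation (prior degrees of freedom 4.85, prior SD 0.203 on the log2 scale). Each group was tested against 0, and each pair of groups against each other, two-sided, over the genes with both replicates in each group involved; 4216 genes were tested in at least 1 comparison. Benjamini-Hochberg adjusted p under 0.05 was the threshold throughout. A ratio tested against 0 leaves out the spread of the control itself, and the labels do not say whether the control RNA was 1 pool. If it was, its deviation is common to all 3 comparisons with it and cancels in the pairwise ones where the signs are right, while with 1 transfectant of a pair turned it would add. Labels do not say that samples 1 and 2 came from separate cultures, so the p-values measure only the spread between these samples. Correlations between transfectants are across genes, which are not independent replicates, and carry no p.

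A shared control was simulated 100 times in data with no transfectant effect, with the control deviating by 0, 0.5 or 1 SD of a replicate; how far the real control deviates cannot be measured here. A self-test on simulated data with known signs and known changes recovered the sign of 12 of 12 arrays. At log2 1 it recovered 98.9% of changed genes for Snail (of 3767 genes in that step), 98.9% for Slug (4052) and 95.8% for E47 (3965). At log2 2 the share was 100.0% in each, and 3, 4 and 3 unchanged genes were called. CDH1 was made to fall in every transfectant of these data, so only the signs of arrays relative to each other were put to the test. The control was given no deviation of its own there, so the unchanged genes called leave out that source. Noise was normal at the moderated SD of each gene, with an assumed dye bias and no discordant samples. The recovered shares need not hold in the real data.

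Before the data were examined, 21 gene lists were fixed, among them EMT transcription factors, inhibitors and targets of bHLH factors, epithelial junctions and polarity, epithelial keratins and differentiation, mesenchymal markers, collagens and extracellular matrix, integrins and matrix receptors, proteases and their inhibitors, TGF-beta and BMP signalling, Wnt and beta-catenin signalling, cell cycle and DNA replication, apoptosis, angiogenesis and hypoxia, growth factor receptors and MAPK signalling, interferon response and antigen presentation, heat shock and stress response, glycolysis and lipid metabolism, ribosomal and translation genes, and markers of leukocytes and of endothelium as other cell types. The result of 1 further list is not reported here. EMT stands for epithelial to mesenchymal transition. limma's camera tested each list with at least 5 measured members against the other genes, with its preset correlation of 0.01, adjusted over lists within a comparison; camera with an estimated correlation and fry were run beside it. Against the control all 3 were planned; between transfectants, the list tests were added after the data were seen.

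The rule for named genes was also fixed then. It takes the targeted genes and the measured EMT factors, the 10 largest rises and falls per comparison with the control among genes past the threshold and on the same side on all 4 arrays, and up to 4 members per list with the smallest adjusted p. It adds the 8 genes per direction with the largest change common to all 3 transfectants and the 6 per direction with the largest difference per pair.

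Alternatives planned before the data were examined were median centring of each array, scaling of all arrays to 1 spread, either array as enough for a replicate, genes with all 6 replicates, all 12 arrays in 1 fit with a dye term and the replicate as random effect or with arrays counted as independent, arrays titled Cy5 or Cy3 alone, each probe on its own, robust moderation, a replicate block, fits of only the groups compared, a 2-fold minimum, adjusted p under 0.01, the other list tests, and each replicate left out. Those chosen after seeing the data were signs by the label dyes, signs as deposited, each transfectant turned the other way (with its largest differences per pair), replicates formed by the titled dye, the label dye as term, the list tests between transfectants, and the fit without the E47 1 array titled Cy3. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.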

Results

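Snail, Slug and E47 are transcription factors known to repress CDH1, the gene of the junction protein E-cadherin; Snail and Slug are zinc finger proteins encoded by SNAI1 and SNAI2, and E47 is a helix-loop-helix product of TCF3. MDCK cells transfected with each factor were compared with MDCK-CMV control cells on 12 arrays, 4 per transfectant, from 2 numbered samples each. The arrays carried values for 10654 to 12982 of 13056 probes. Across genes, the replicates of a transfectant correlated with r = 0.65 in Snail, 0.72 in Slug and 0.73 in E47, and their median absolute difference was 0.225, 0.206 and 0.18 on the log2 scale. Duplicate spots of 2093 clones correlated with r between 0.30 and 0.86 within an array.

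CDH1 and SNAI1 moved apart in the Snail transfectant. The first CDH1 clone had a mean log2 ratio of -2.88 ± 0.36 (SD, n = 2 replicates) in Snail, -3.21 ± 0.21 in Slug and -2.74 ± 0.68 in E47, and the second clone had -3.57 ± 0.53, -4.12 ± 0.26 and -3.77 ± 0.50. For the second clone these are 11.9-fold, 17.3-fold and 13.6-fold lower levels than in the control, on 4 of 4 arrays in each transfectant. The third CDH1 clone did not follow, with 0.23 ± 0.02, -0.06 ± 0.12 and 0.29 ± 0.03. SNAI1 lay above the control in Snail by 1.70 ± 0.95 (SD, n = 2), on arrays between 0.87 and 2.94. TCF3 had a log2 ratio of 0.71 ± 0.15 in E47 and 1.11 ± 0.01 in Slug, above 0 on 4 of 4 arrays of each, and of -0.05 ± 0.25 in Snail.

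**Figure D1:**
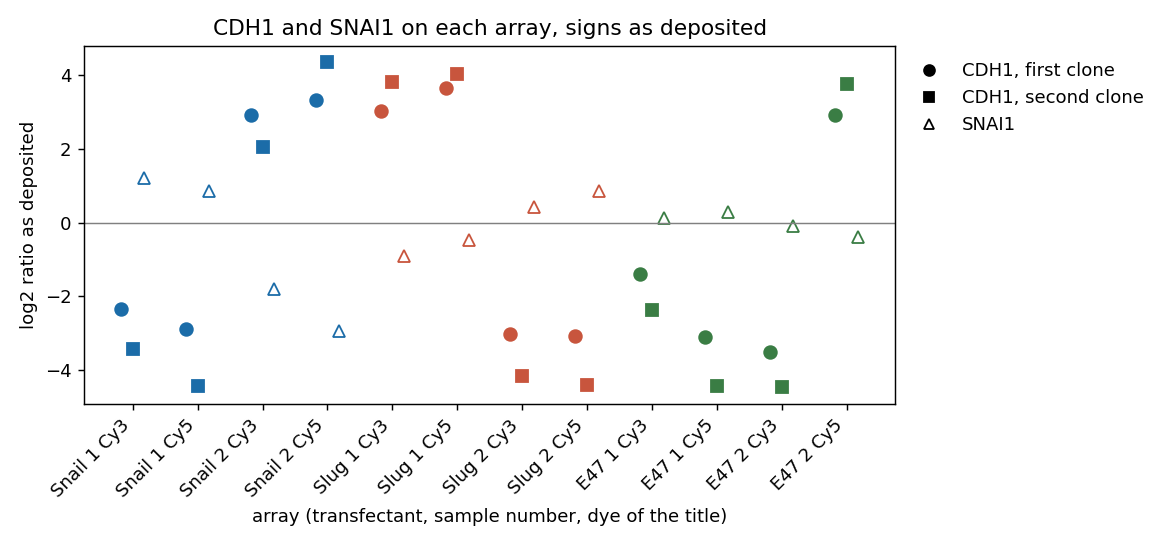
Log2 ratio as deposited (vertical axis) of the first and second CDH1 clone and of SNAI1 on each of the 12 arrays (horizontal axis), 1 point per array. Both CDH1 clones lie above 0 on 5 arrays and below 0 on 7, and on the 4 Snail arrays SNAI1 lies on the side opposite to CDH1.

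These directions are assumed. As deposited, arrays of the same transfectant with opposite apparent orientation correlated with a mean r of -0.51 (11 pairs) and those with the same orientation with 0.48 (7 pairs), but the orientation did not follow the dyes of the labels, and the labels do not name the numerator. Signs were set so that CDH1 was below the control. SNAI1, above the control on all 4 Snail arrays once CDH1 is below, gives Snail a second gene that places the sign; for E47, TCF3 does so, though TCF3 was also higher in Slug; for Slug, the sign rests on CDH1 alone. The labels do not give the constructs, so whether these probes read the introduced genes is unknown. With the sign of a transfectant turned, its higher and lower genes exchange, while genes on the side of CDH1 stay on that side.

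The comparison of Snail with the control asks which genes a Snail transfectant expresses at another level. Opposite to CDH1 rose SPARC, a secreted matrix protein, by 5.36 ± 0.88 on the log2 scale (SE, n = 2; adjusted p = 0.0119), which is 41.1-fold, CALD1, the actin-binding caldesmon, by 2.74 ± 0.52 (adjusted p = 0.0192), LUM, a proteoglycan, by 2.16 ± 0.26 (adjusted p = 0.0038) and COL1A2, a chain of type I collagen, by 1.99 ± 0.23 (adjusted p = 0.0037). Falling with CDH1, DSP, the desmosome protein desmoplakin, had a log2 ratio of -2.51 ± 0.12 (adjusted p = 1.72e-04), and FXYD3, a regulator of ion transport, -2.99 ± 0.24 (adjusted p = 0.0014). RGS2, a regulator of G protein signalling, fell to -3.29 ± 0.18 (adjusted p = 1.93e-04), SPP1, the secreted osteopontin, to -3.26 ± 0.28 (adjusted p = 0.0017) and IL1RN, the interleukin-1 receptor antagonist, to -2.97 ± 0.26 (adjusted p = 0.0017). MYC was at -1.63 ± 0.18 (adjusted p = 0.0036) and CCND1, cyclin D1, at -0.80 ± 0.12 (adjusted p = 0.0088). Each SE rests on the spread pooled over the 3 transfectants. For SPARC and CALD1 that pool holds Slug replicates far apart (4.17 and -0.67, and 1.96 and -0.64). On the Snail arrays themselves SPARC lay between 5.15 and 5.64. The calls of SPARC (5.48 and 5.24), CALD1 (3.20 and 2.28) and CCND1 (-0.69 and -0.91) were lost without Snail replicate 1 or 2, and those of COL1A2 (1.87) and SNAI1 (1.04) without replicate 2.

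Among genes on the same side of 0 on all 4 Snail arrays, which the naming rule requires, the other largest rises were SCD5 (2.91), PTPRM (1.96), MLF1 (1.79), RARRES2 (1.78), ANXA5 (1.75) and SNAI1 itself (1.70, adjusted p = 0.0092). The other largest falls were TFF1 (-2.34), PTPRZ1 (-2.15), CDH1 (-2.07 over its clones), SLCO2A1 (-2.05) and NID2 (-2.01). PTPRZ1 had -0.91 and -3.39 in replicates 1 and 2 (adjusted p = 0.0483) and lost its call without replicate 2. In all, 272 of 3768 genes passed adjusted p of 0.05 in limma, 81 higher and 191 lower, or 191 higher and 81 lower with the sign turned; 91 differed at least 2-fold. Without Snail replicate 1 the count was 105 (46 higher and 59 lower), and without Snail replicate 2 it was 34 (2 and 32), so the split moved as well. With no transfectant effect and a shared control that deviated by 1 replicate SD, simulated data gave a median of 199.5 calls (highest 350), and with 0.5 SD a median of 3 (highest 24), so the count alone does not separate a response from a deviating control.

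Of the gene groups, only epithelial junctions and polarity passed camera in Snail, downward (adjusted p = 1.07e-04; adjusted p = 0.72 with an estimated correlation): 3 of 16 members fell, DSP, CDH1 and CTNNA1, the alpha-catenin of adherens junctions (-0.86, adjusted p = 0.010), none rose and 13 did not pass; adjusted over the list alone, 6 fell. CDH1, which set the sign, is a member of this junction list, and the list was not tested without it. Keratins and differentiation had 2 of 11 lower, KRT7 (-1.0) and MAL (-0.61), with 3 adjusted over the list alone (adjusted p = 0.128). Mesenchymal markers went both ways: SPARC, CALD1 and FN1, fibronectin (1.01, adjusted p = 0.0161), rose, THY1 (-0.82) fell and 6 of 10 did not pass (adjusted p = 0.613). So did collagens and matrix, with 4 of 25 higher and 3 lower (adjusted p = 0.613), where COL1A2 and LUM rose and SPP1 and BGN (-1.03) fell. Among EMT transcription factors 1 of 6, SNAI1, the gene of Snail itself, rose (adjusted p = 0.128). Integrins had 1 of 23 higher, VCL (0.66), and 1 lower, ITGA6, a laminin receptor subunit (-1.54); adjusted over the list alone, 2 were higher and 1 lower (adjusted p = 0.773). Proteases had 2 of 28 higher, CTSK (1.12) and TIMP1 (1.27), and 2 lower, MMP14, a membrane metalloproteinase (-1.60), and TIMP3 (-1.26); adjusted over the list alone, 5 were higher and 2 lower (adjusted p = 0.149).

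The remaining lists did not pass in Snail; counts adjusted over the list alone are the same as those given unless stated. TGF-beta and BMP signalling had 1 of 29 higher, CCN2 (0.60), and 0 adjusted over the list alone (adjusted p = 0.128). Wnt signalling had 1 of 27 higher, FZD7, and 2 lower, MYC and CCND1, with 4 higher and 2 lower over the list alone (adjusted p = 0.773). Cell cycle genes had 2 of 41 higher and 5 lower, among them MCM5 (-0.95), with 3 and 7 over the list alone (adjusted p = 0.773). Apoptosis had 1 of 32 higher, TNFSF10 (1.06), and 1 lower, TNFRSF1B (-0.83; adjusted p = 0.773). Angiogenesis and hypoxia had 1 of 23 higher, ENO1, with 3 higher and 1 lower over the list alone (adjusted p = 0.773). Growth factor and MAPK genes had 2 of 41 higher, SPRY1 and SPRY2, and 1 lower, MYC, with 3 and 4 over the list alone (adjusted p = 0.773). Interferon genes had 2 of 25 lower, CD74 and ISG15 (adjusted p = 0.839). Stress genes had 1 of 20 higher, MT1X, and 1 lower, ATF4 (-0.95), with 2 and 2 over the list alone (adjusted p = 0.883). Glycolysis and lipid genes had 1 of 15 higher, ENO1 (0.83), and 1 lower, PPARG (-1.16), with 3 and 2 over the list alone (adjusted p = 0.883). Ribosomal genes had 1 of 20 higher, RPL31, and 2 lower, RPS21 and EEF1D, with 2 and 3 over the list alone (adjusted p = 0.696). No member passed among 7 bHLH inhibitors and targets (adjusted p = 0.773), 19 leukocyte markers (adjusted p = 0.773) or 10 endothelial markers (adjusted p = 0.773). Median, mean and test differed in sign for the integrin, Wnt, apoptosis, angiogenesis, glycolysis and leukocyte lists, none of them past the test. In place of 1 list, 2 passed without Snail replicate 1 or 2 and 4 without Slug replicate 1 or 2.

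The comparison of Slug with the control asks the same of a Slug transfectant. Rising opposite to CDH1 were LUM by 3.93 ± 0.26 (SE, n = 2; adjusted p = 4.25e-04), which is 15.2-fold, ITGA5, the fibronectin receptor subunit, by 3.43 ± 0.43 (adjusted p = 0.0032), TIMP1, an inhibitor of metalloproteinases, by 2.96 ± 0.20 (adjusted p = 6.55e-04), WNT5A, a Wnt ligand, by 2.79 ± 0.65 (adjusted p = 0.0206) and FN1 by 2.00 ± 0.18 (adjusted p = 8.08e-04). CDKN1A, an inhibitor of cyclin-dependent kinases, rose by 2.35 ± 0.39 (adjusted p = 0.0060) and VEGFA, an angiogenic growth factor, by 1.99 ± 0.13 (adjusted p = 4.25e-04). Falling with CDH1 were SPP1 (-3.78 ± 0.28, adjusted p = 5.12e-04), FXYD3 (-3.48 ± 0.24, adjusted p = 4.63e-04), DSP (-1.67 ± 0.12, adjusted p = 5.12e-04) and KRT19, an epithelial keratin (-2.19 ± 0.26, adjusted p = 0.0043). SPARC differed between the samples: its log2 ratio was 4.17 in replicate 1 and -0.67 in replicate 2, and its mean did not pass (adjusted p = 0.195). Among the genes above, WNT5A lost its call without Slug replicate 1 (3.15) or 2 (2.42).

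Under the same rule, further large rises in Slug were SIRPA (2.47), BHLHE40 (2.37), SCD5 (2.29), LDB2 (2.17) and TCF4 (2.11). Further large falls were PTPRZ1 (-2.98), IL1RN (-2.82), CDH1 (-2.46 over its clones), RGS2 (-2.40), ATP4A (-2.33), SRGN (-2.11) and SLC2A3 (-2.03). In limma 885 of 4053 genes passed, 495 higher and 390 lower, or 390 higher and 495 lower with the sign turned; 207 differed at least 2-fold. Slug arrays had wider ratios (SD 0.640 to 0.695, other arrays 0.446 to 0.586), and with all arrays scaled to 1 spread 440 genes passed. Without Slug replicate 1 the count was 339, with 63.4% of them higher, and without Slug replicate 2 it was 602, with 55.8%. The simulated control deviating by 1 replicate SD gave a median of 211 calls and at most 390, and by 0.5 SD a median of 3 and at most 21.

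Among EMT transcription factors in Slug, 4 of 6 rose, TCF4 (adjusted p = 0.0125), TWIST1 (1.84, adjusted p = 0.0077), TCF3 (1.11, adjusted p = 0.0021) and ZEB1 (0.89, adjusted p = 0.0137), and SNAI1 (0.67) and KLF8 (-0.07) did not pass; the list passed camera upward (adjusted p = 0.0158; adjusted p = 0.324 with an estimated correlation), and 5 rose adjusted over the list alone. Growth factor receptors and MAPK genes had 14 of 43 higher and 0 lower (16 higher adjusted over the list alone), among them JUND (1.5), FGFR1 (1.48), EGR1 (1.07) and IGF2R (0.81), and passed upward (adjusted p = 0.0048; adjusted p = 0.324 with an estimated correlation). TGF-beta and BMP genes had 9 of 29 higher, with CCN2 (1.17), INHBA (1.12), BMP2 (0.91) and INHBB (0.80), and 2 lower, or 11 and 2 adjusted over the list alone (adjusted p = 0.0215; adjusted p = 0.324 with an estimated correlation). Wnt genes had 9 of 29 higher and 0 lower, with WNT5B (1.23), TLE1, a corepressor (1.04), CCND1 (0.69) and FZD7 (0.69); the counts were the same adjusted over the list alone (adjusted p = 0.0396; adjusted p = 0.324 with an estimated correlation). Collagens and matrix had 6 of 26 higher, among them LUM, HSPG2 (2.10) and FN1, and 2 lower, among them SPP1, also when adjusted over the list alone (adjusted p = 0.0215; adjusted p = 0.400 with an estimated correlation). Junctions and polarity passed downward (adjusted p = 0.0354, or 0.619 with an estimated correlation): CDH1, DSP and DSG2 (-1.18) fell, JUP, plakoglobin (0.82), rose and 13 of 17 did not pass, also when adjusted over the list alone, with a median of -0.03 and a mean of -0.39. Here too CDH1 set the sign, and the list was not tested without it. After scaling all arrays to 1 spread, the junction and Wnt lists no longer passed, and without Slug replicate 1 only 3 lists passed in place of 6.

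The other lists did not pass camera in Slug, and counts adjusted over the list alone are the same as those given unless stated. Keratins and differentiation had 1 of 13 higher, SFN (1.04), and 4 lower, among them ANXA3 (-1.51) and MAL (adjusted p = 0.0905). Mesenchymal markers had 3 of 12 higher, FN1, CDH6 (1.19) and ENG (1.05; adjusted p = 0.116). bHLH inhibitors and targets had 2 of 8 higher, CDKN1A and ID3 (0.84; adjusted p = 0.445). Integrins had 6 of 25 higher, with ITGA5, ITGA10 (1.03) and SDC4, and 3 lower, with ITGB6 (-2.02), or 7 and 3 over the list alone (adjusted p = 0.386). Proteases had 1 of 26 higher, TIMP1, and 2 lower, MMP14 (-0.97) and ADAM10 (-0.94; adjusted p = 0.964). Cell cycle genes had 10 of 42 higher and 5 lower, with E2F1 (1.42) and PLK1 (0.93) higher and BUB1 (-1.60) and MAD2L1 (-0.96) lower, or 11 and 5 over the list alone (adjusted p = 0.609). Apoptosis had 5 of 34 higher, with BCL2L1 (1.5), and 3 lower, MCL1 (-0.98), BCL2A1 and CYCS (adjusted p = 0.964). Angiogenesis and hypoxia had 4 of 27 higher, VEGFA, SLC2A1, PGK1 and TEK, and 1 lower (adjusted p = 0.116). Interferon genes had 2 of 29 higher, with IFI35, and 3 lower, with PSMB8, or 1 and 2 over the list alone (adjusted p = 0.537). Stress genes had 5 of 20 higher, with ATF3 (1.05), DNAJB2 and ATF4 (0.81), and 2 lower (adjusted p = 0.0603). Glycolysis and lipid genes had 4 of 16 higher, with ALDOA (1.46) and PKM (1.39), and 2 lower, with PPARG (adjusted p = 0.116); with the arrays titled Cy5 alone PKM was at -0.30. Ribosomal genes had 2 of 19 higher, EEF1D and EEF2, and 3 lower, with RPL22 (-1.0), or 2 and 5 over the list alone (adjusted p = 0.142). Leukocyte markers had 1 of 18 higher, BTK, and 2 lower, PTPRC and ITGAX (adjusted p = 0.904), and endothelial markers had 3 of 11 higher, ENG, EGFL7 and TEK (adjusted p = 0.717); with the arrays titled Cy5 alone EGFL7 was at -0.20. Median, mean and test differed in sign for the leukocyte and endothelial lists.

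The comparison of E47 with the control asks the same of an E47 transfectant. Here 4 inhibitors of helix-loop-helix factors rose opposite to CDH1: ID3 by 1.56 ± 0.19 (SE, n = 2; adjusted p = 0.0045), ID4 by 1.49 ± 0.17 (adjusted p = 0.0034), ID2 by 1.06 ± 0.17 (adjusted p = 0.0146) and ID1 by 0.86 ± 0.17 (adjusted p = 0.0298). SPARC rose by 4.69 ± 0.88 (adjusted p = 0.0240), which is 25.8-fold, COL1A2 by 3.02 ± 0.23 (adjusted p = 8.34e-04), GAS1, a growth arrest gene, by 2.95 ± 0.15 (adjusted p = 1.24e-04) and CALD1 by 2.26 ± 0.52 (adjusted p = 0.0478). Falling with CDH1 were RGS2 (-3.51 ± 0.18, adjusted p = 1.24e-04), SPP1 (-3.02 ± 0.28, adjusted p = 0.0015), FXYD3 (-2.89 ± 0.24, adjusted p = 8.34e-04) and KRT7, a keratin of simple epithelia (-1.34 ± 0.15, adjusted p = 0.0030). TWIST1, a helix-loop-helix factor of EMT, rose by 1.99 ± 0.33 (adjusted p = 0.0151). The pooled SEs of SPARC and CALD1 again include the Slug replicates that lay far apart. On the E47 arrays themselves SPARC lay between 4.29 and 5.25. The calls of SPARC (4.38 and 5.0) and CALD1 (1.94 and 2.57) were lost without E47 replicate 1 or 2 and, with values as above, without either Snail replicate, and those of TWIST1 (1.21), ID4 (1.17), ID2 (0.70) and ID1 (0.51) without E47 replicate 2. ID1 also lost its call without either Snail replicate.

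Under the same rule, further large rises in E47 were TMEFF1 (2.70), CXXC5 (2.49), ITM2B (2.38), GNAI1 (2.21), ITGA7 (2.11) and SCD5 (2.08). Further large falls were TSPAN13 (-2.44), FGFBP1 (-2.37), IL1RN (-2.15), SLCO2A1 (-2.12), CDH1 (-2.07 over its clones), NID2 (-1.98) and TFF1 (-1.79). In limma 210 of 3966 genes passed, 151 higher and 59 lower, or 59 higher and 151 lower with the sign turned; 80 differed at least 2-fold. Without E47 replicate 1 the count was 109 (75 higher and 34 lower), without E47 replicate 2 it was 26 (15 and 11), and without the E47 1 array titled Cy3 alone it was 368. A simulated control deviating by 1 replicate SD gave a median of 204.5 calls and at most 373, and by 0.5 SD a median of 2 and at most 25, so this count alone does not separate a response from a deviating control either.

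In E47, bHLH inhibitors and targets passed camera upward (adjusted p = 5.54e-05; adjusted p = 0.300 with an estimated correlation), with ID1 to ID4 as the 4 of 8 members past the test; the count was the same adjusted over the list alone. EMT factors had 2 of 6 higher, TWIST1 and TCF3, and 3 adjusted over the list alone (adjusted p = 0.0217). TCF3 is the gene of E47 itself, and the list was not tested without it. Mesenchymal markers had 4 of 12 higher and 0 lower, SPARC, CALD1, FN1 (1.13) and CDH6 (1.16), also adjusted over the list alone (adjusted p = 0.0286). Integrins had 4 of 24 higher, ITGA7, VCL (1.24), ITGAV (1.15) and SDC4 (0.98), with 6 higher and 2 lower adjusted over the list alone (adjusted p = 0.0286). Growth factor and MAPK genes had 5 of 44 higher, with SPRY2, an inhibitor of receptor signalling (1.70), EGR1 (1.01), EREG (0.94) and JUND (0.75), and 8 adjusted over the list alone (adjusted p = 0.0133). TGF-beta and BMP genes had 5 of 29 higher, with ACVR1 (1.36), CCN2 (1.06), INHBB (0.91) and SMAD7, an inhibitor of that pathway (0.80), and 1 lower, also adjusted over the list alone (adjusted p = 0.0250). Wnt genes had 3 of 28 higher, FZD6 (0.76), FZD7 (0.73) and CCND1 (0.73), also adjusted over the list alone (adjusted p = 0.0426). Glycolysis and lipid genes had 3 of 15 higher, PKM (0.96), ALDOA (0.76) and PFKM (0.59), and 5 adjusted over the list alone (adjusted p = 0.0350). With an estimated correlation, each of the 7 lists after the first had adjusted p = 0.300.

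Downward in E47, keratins and differentiation passed with KRT7 and ANXA3 (-1.61) lower, SFN (0.80) higher and 8 of 11 not past the test, also adjusted over the list alone (adjusted p = 0.0286; adjusted p = 0.300 with an estimated correlation). Ribosomal genes passed with 0 of 19 members past the test, also adjusted over the list alone, and a median of -0.19 (adjusted p = 0.0434; adjusted p = 0.300 with an estimated correlation). Junctions and polarity passed with CDH1 and DSP (-0.67) lower and GJA1, connexin 43 (1.00), higher, while 14 of 17 did not pass, or 1 higher and 3 lower adjusted over the list alone (adjusted p = 0.0286, or 0.518 with an estimated correlation). The list median was -0.05, CDH1 set the sign, and the list was not tested without CDH1. In place of 11 lists, 6 passed without the E47 1 array titled Cy3, 7 without E47 replicate 1 and 3 without E47 replicate 2.

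The other E47 lists did not pass; counts adjusted over the list alone are the same as those given unless stated. Collagens and matrix had 3 of 24 higher, with COL1A2 and FN1, and 3 lower, with SPP1 and NID2 (adjusted p = 0.709). Proteases had 1 of 26 higher, MMP19 (0.66), and 2 lower, MMP14 (-1.73) and PLAU, urokinase (-0.94), or 3 and 3 over the list alone (adjusted p = 0.590). Cell cycle genes had 1 of 43 higher, CCND1, or 7 higher and 2 lower over the list alone (adjusted p = 0.793). Apoptosis had 1 of 35 higher, DAPK1 (adjusted p = 0.543). Angiogenesis and hypoxia had 2 of 25 higher, VEGFA (1.20) and VEGFC (0.89), or 3 higher and 1 lower over the list alone (adjusted p = 0.459). Stress genes had 2 of 19 higher, the metallothioneins MT1X (1.84) and MT2A (1.46), and 1 lower, ATF4 (adjusted p = 0.210). No member passed among 29 interferon genes (adjusted p = 0.144), 20 leukocyte markers (adjusted p = 0.673) or 11 endothelial markers (adjusted p = 0.709). Median, mean and test differed in sign for the protease, cell cycle, leukocyte and endothelial lists. No list passed with an estimated correlation in any transfectant, and fry, which tests whether the genes of a list move on balance one way, passed 0 lists in Snail, 12 in Slug and 12 in E47.

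**Figure D2:**
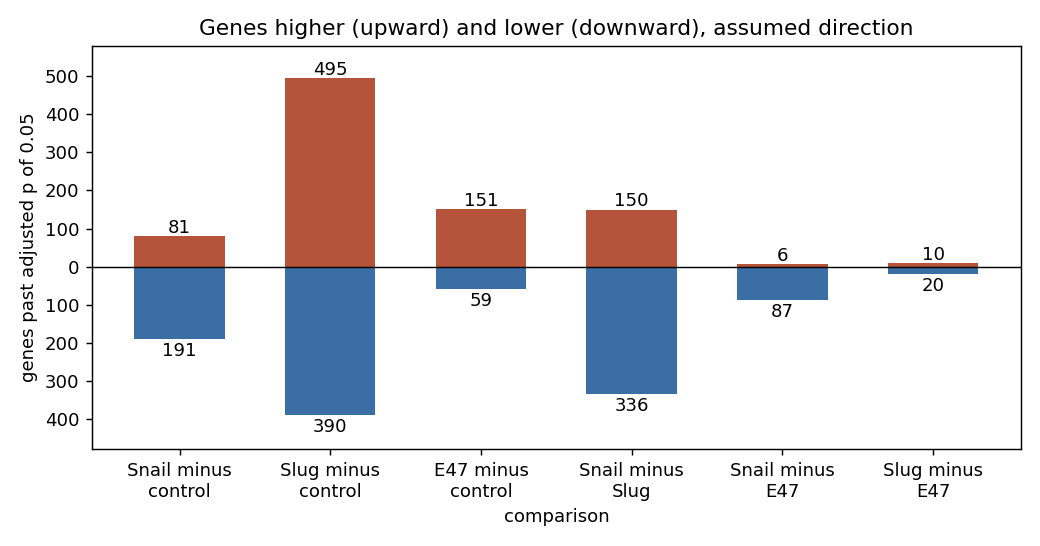
Number of genes past adjusted p of 0.05 in limma (vertical axis), higher as bars upward and lower as bars downward, for each comparison (horizontal axis), in the assumed direction. Slug against control has 495 genes higher and 390 lower, and Slug against E47 has 10 and 20.

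The series asks what the 3 repressors have in common. In all 3 transfectants SCD5, a fatty acid desaturase, COL1A2 and FN1 rose together with CAMK2N1 (1.21 in Snail, 1.30 in Slug and 1.53 in E47), ITGBL1 (0.76, 1.37 and 1.86), FKBP2 (0.96, 1.62 and 0.93), MCAM, an adhesion molecule (1.01, 0.77 and 1.02), and SERPINH1, a collagen chaperone (0.97, 0.96 and 0.75). SPP1, FXYD3, RGS2, IL1RN, CDH1 and SLCO2A1 fell in all 3, as did FGFBP1 (-1.93, -1.60 and -2.37) and PLSCR1 (-1.56, -1.67 and -1.69). CDH1 lies below 0 in all 3 by the choice of sign and is counted among the shared genes. In limma 35 of 3537 genes passed the same way in all 3, 14 higher and 21 lower, where independent lists of these sizes would share 0.37 and 0.30. A shared control that deviated by 1 replicate SD gave a median of 34 such genes in simulated data (highest 79), and by 0.5 SD a median of 0 (highest 2), so the count alone does not separate a common response from a deviating control. The count was 10 without Snail replicate 2 and 12 without E47 replicate 2, and with the Snail, Slug or E47 arrays turned the other way it was 4, 1 or 0.

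**Figure D3:**
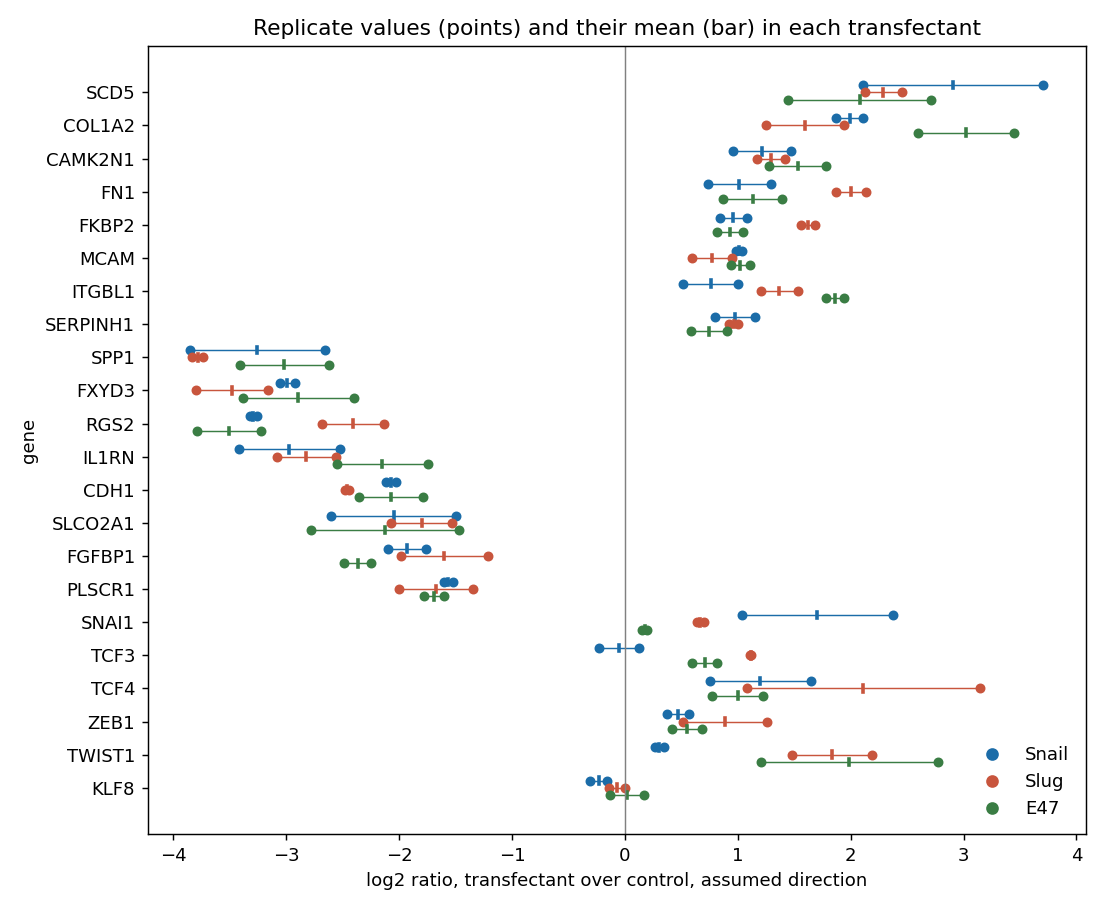
Log2 ratio of transfectant over control in the assumed direction (horizontal axis) for genes changed in all 3 transfectants, the targeted genes and EMT factors (vertical axis); points are the 2 replicates, bars their mean, colours the transfectants. SCD5 lies above 0 in all 6 replicates and SPP1 below 0 in all 6, while SNAI1 is highest in Snail and TWIST1 lies nearer 0 in Snail than in Slug and E47.

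In pairs, Slug and E47 shared 78 higher and 40 lower genes (18.1 and 5.7 by independent lists) and had 5 in opposite directions, Snail and E47 shared 25 and 31 (3.1 each) with 4 opposite, and Snail and Slug shared 31 and 60 (9.9 and 18.1) with 18 opposite. Independent lists leave out the shared control, which alone gave medians of 66.5, 63 and 65 genes common to these pairs at 1 SD in simulated data (highest 144, 132 and 150) and of 0 at 0.5 SD. Across genes, fold changes of Slug and E47 correlated with Pearson's r = 0.62 and a Spearman rank correlation of 0.55, those of Snail and E47 with 0.43 and 0.16, and those of Snail and Slug with 0.29 and 0.09. At 1 SD the simulated control alone gave Pearson's r of 0.66, 0.67 and 0.67 and rank correlations of 0.643, 0.642 and 0.644, each above the observed one. At 0.5 SD its Pearson's r was 0.336, 0.331 and 0.331 (highest 0.377, 0.381 and 0.38), and its rank correlations, 0.313 to 0.316, lay above the 2 that involve Snail. The simulated data held no transfectant effects. Effects of 1 transfectant alone would lower a correlation, so these correlations do not tell what the control brings. The covariance of fold changes was 0.118 for Slug and E47, 0.067 for Snail and E47 and 0.059 for Snail and Slug. The simulated control gave 0.050, 0.050 and 0.051 at 1 SD (highest 0.057, 0.056 and 0.056), about the same for each pair. At 0.5 SD it gave 0.013, 0.012 and 0.013. With 1 transfectant of a pair turned, the correlations are -0.62, -0.43 and -0.29.

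Pairwise comparisons ask where the repressors differ. The control cancels there only if it was the same RNA on all arrays and if the assumed signs are right. The labels do not say whether the RNA was the same. The simulated medians below take both as given, so values near 0 were built in and do not test the control. Between Snail and Slug, VEGFA (log2 difference -2.27 ± 0.18, SE, adjusted p = 0.0032), the growth factor HDGF (-2.36 ± 0.19, adjusted p = 0.0032) and SRSF4, a splicing factor (-2.50 ± 0.23, adjusted p = 0.0032), were lower in Snail. So were MYC (-1.55, adjusted p = 0.0127), CCND1 (-1.49, adjusted p = 0.0050) and JUND (-1.94, adjusted p = 0.0032). ATP4A was higher in Snail (2.43 ± 0.25, adjusted p = 0.0042). Growth factor and MAPK genes were lower in Snail as a list (adjusted p = 0.0064; adjusted p = 0.83 with an estimated correlation and 0.0194 with fry). Of its members, 1 of 41 was higher and 9 lower, or 1 and 21 adjusted over the list alone. SPARC did not pass (3.61 ± 1.24, adjusted p = 0.0951). In limma 486 of 3675 genes differed, 150 higher in Snail and 336 lower, and 228 of them at least 2-fold; the simulated control gave a median of 0. The count was 141 without Snail replicate 1 (55 higher and 86 lower), 138 without Snail replicate 2 (30 and 108), 221 without Slug replicate 1 (56 and 165), and 389 without Slug replicate 2 (131 and 258). It was 671 with either transfectant turned, 363 higher and 308 lower with Snail turned and the reverse with Slug turned.

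Between Snail and E47, GAS1 (-2.73 ± 0.21, adjusted p = 0.0054), ITGA6 (-2.13 ± 0.21, adjusted p = 0.0086), HDGF (-2.19 ± 0.19, adjusted p = 0.0058), DSP (-1.84 ± 0.17, adjusted p = 0.0080), MYC (-1.85, adjusted p = 0.0205) and CCND1 (-1.52, adjusted p = 0.0132) were lower in Snail. LUM (1.91 ± 0.36, adjusted p = 0.0421) and PLAU (1.41 ± 0.26, adjusted p = 0.0384) were higher. bHLH inhibitors and targets were lower in Snail as a list (adjusted p = 0.0151; adjusted p = 0.791 with an estimated correlation and 0.115 with fry), with ID4 (-1.44) and ID3 (-1.33) past the test among 7 members and 4 adjusted over the list alone. Growth factor and MAPK genes were lower too (adjusted p = 0.0151; adjusted p = 0.791 with an estimated correlation and 0.0282 with fry), with 0 of 41 higher and 6 lower, or 1 and 9 adjusted over the list alone. Ribosomal genes passed camera upward (adjusted p = 0.0344; adjusted p = 0.791 with an estimated correlation and 0.0818 with fry), although the only member past the test, EEF1D (-1.24), was lower; adjusted over the list alone, 4 were higher and 3 lower. In limma 93 of 3617 genes differed, 6 higher in Snail and 87 lower. The simulated control, which cancels by its design, gave a median of 0. The count was 13 without Snail replicate 1 (5 higher and 8 lower), 14 without Snail replicate 2 (0 and 14), 42 without E47 replicate 1 (1 and 41), and 3 without E47 replicate 2 (0 and 3). It was 199 without the E47 1 array titled Cy3 and 357 with either transfectant turned, 195 higher and 162 lower with Snail turned and the reverse with E47 turned.

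Between Slug and E47, LUM was higher in Slug (3.68 ± 0.36, adjusted p = 0.0144), as were ATF4, a stress response factor (1.46 ± 0.17, adjusted p = 0.0180), and DDIT4 (1.42 ± 0.19, adjusted p = 0.0355). GAS1 (-2.54 ± 0.21, adjusted p = 0.0098), GNAI1 (-2.12 ± 0.22, adjusted p = 0.0144), ITGA7 (-2.10 ± 0.28, adjusted p = 0.0283), ID2 (-1.47 ± 0.24, adjusted p = 0.0473) and SPRY2 (-1.25 ± 0.17, adjusted p = 0.0310) were lower in Slug. In limma 30 of 3816 genes differed, 10 higher in Slug and 20 lower, and no list passed camera; the simulated control gave a median of 0. The count was 15 without either Snail replicate (3 higher and 12 lower), 14 without Slug replicate 1 (4 and 10), 27 without Slug replicate 2 (11 and 16), and 8 without either E47 replicate (2 and 6, or 3 and 5). It was 66 without the E47 1 array titled Cy3 and 985 with either transfectant turned, 411 higher and 574 lower with Slug turned and the reverse with E47 turned.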

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

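Of the tests weighed here, those on scaling to 1 spread and on closer replicates were chosen before their result was seen, and the others after.

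The signs of the arrays do not follow the dyes of the labels: both arrays of Snail 1 and Slug 2 run one way as deposited and both arrays of Snail 2 and Slug 1 the other. A dye bias, shared by all arrays, would make arrays of different transfectants with opposite orientation correlate above 0, and their mean correlation was -0.25; for E47, an interchange of sample number and dye in the titles would make the E47 2 arrays correlate above 0, and they correlated with r = -0.74. For Snail and Slug an interchange cannot be told apart by correlation: arrays of the 2 numbers would be 1 sample where the titled dye is the same and correlate more strongly than others, but the mean absolute r differed by -0.02 over 4 pairs against 4 (SD 0.09). SPARC was alike within each Slug number (3.78 and 4.57, against -0.74 and -0.59). An interchange would make that gap an effect of dye orientation, which for SPARC was at most 0.53 in Snail and E47. This is 1 gene picked for its gap and does not settle the titles. Opposite responses of the samples cannot be told apart either: the highest SNAI1 spot of Snail 2 was -1.77 as deposited, but the labels give neither the construct nor the numerator, which was not tested and stays open. If the titles are interchanged, the replicates of Snail and Slug mix the numbered samples, and replicates formed by the titled dye gave 557 genes in Snail in place of 272.

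SPARC was at 4.17 in Slug replicate 1 and -0.67 in replicate 2, while it lay between 4.29 and 5.64 on the Snail and E47 arrays. An effect of dye orientation would show in the other transfectants, where orientations differed by at most 0.53 (0.25 in Snail). A wholly different sample under the label Slug 2 would not resemble Slug 1, but its correlation with Slug 1, 0.72, exceeded its highest with another transfectant, 0.54, by 0.18. A failed spot cannot be told apart from a low level, since both Slug 2 arrays gave like values (-0.74 and -0.59, a difference of 0.15), as a failure common to both would. Across probes, the 2 Slug 2 arrays correlated with r = 0.31. Slug 2 with Slug 1 arrays gave 0.40 to 0.60 after turning. A difference between the 2 Slug samples in SPARC stays open and was not tested.

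Slug had 3.25 times as many genes past the threshold as Snail, the next transfectant. Fewer missing values on Slug arrays do not account for it, since among genes with all 6 replicates the ratio was 2.92 (847, 290 and 261 genes), nor do closer replicates, since the median difference between Slug replicates was 1.14 times the lower of the others. With all arrays scaled to 1 spread the ratio was 1.24 (440, 355 and 313 genes), so the wider scale of the Slug arrays may be part of it. The excess was also absent with the scale unchanged in fits of only the group compared (539 genes in Slug, 568 in Snail and 391 in E47), while Slug with 1 replicate had 339 or 602 against 345 in Snail with 2. How much the scale and the pooled spread of the fit each bring was not tested, and a larger response, which would widen the arrays too, stays open. Duplicate spots correlated with r of 0.86, 0.48, 0.45 and 0.34 on the Slug arrays and 0.30 to 0.82 on the others. How much disagreement between spots widened the Slug arrays was not tested either.

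Single arrays stood apart from the other 3 of their group in 9 of 113 sets of 4 values; chance gives about 1 in 20. In Slug these were BHLHE40 at 2.80 (others 2.20 to 2.25), RGS2 at -1.71 (others -2.69 to -2.55) and MCAM at 1.31 (others 0.56 to 0.63), all on the Slug 2 array titled Cy3, and COL1A2 at 0.68 on the Slug 1 array titled Cy5 (others 1.83 to 1.95). The E47 1 array titled Cy3 had 1647 missing probes (others 1012 to 1015), a correlation of duplicate spots of 0.30 (others 0.74 to 0.82), SCD5 at 0.43 (others 2.46 to 2.78), RGS2 at -2.60 (others -3.86 to -3.76) and FXYD3 at -1.62 (others -3.41 to -3.18). Each array was set against its own group only, so low values on several arrays of a group are not flagged. Duplicate spots correlated with 0.34 and 0.45 on the Slug 2 arrays titled Cy5 and Cy3. They gave 0.48 on Slug 1 titled Cy5 and 0.44 on Snail 2 titled Cy3. No fit left out any of these arrays alone.

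Transfectants differed from each other by limma's test of the difference itself in 486 genes for Snail and Slug, 93 for Snail and E47 and 30 for Slug and E47. With the assumed signs, the largest log2 differences of Snail minus Slug were ATP4A 2.43, NSMCE2 1.92, NSF 1.88, MRPL1 1.81, TMEM258 1.72, SLC44A1 1.71, PATL1 -2.50, SRSF4 -2.50, SIRPA -2.38, HDGF -2.36, BHLHE40 -2.36 and VEGFA -2.27. For Snail minus E47 they were LUM 1.91, PLAU 1.41, PCLAF 1.05, GPNMB 1.04, COX7A2 0.98, TUBA3C 0.85, GAS1 -2.73, HDGF -2.19, ITGA6 -2.13, EPS8 -2.06, SRSF4 -2.04 and ITGA7 -2.03. For Slug minus E47 they were LUM 3.68, LRRC8C 1.63, TSPAN13 1.60, FBXO7 1.54, ATF4 1.46, DDIT4 1.42, GAS1 -2.54, GNAI1 -2.12, ITGA7 -2.10, PLA2G7 -1.92, ATP4A -1.88 and MT1X -1.63. With the first of a pair turned the other way, genes that move together would differ most instead, SPP1 (7.04) and SPARC (-7.11) for Snail minus Slug, RGS2 (6.80) and SPARC (-10.05) for Snail minus E47 and SPP1 (6.80) and SPARC (-6.45) for Slug minus E47.

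Probes without a gene symbol, which no comparison above uses, also carried signal when each probe was tested on its own in limma: 147 of 2833 passed in Snail (63 higher, 84 lower), 525 of 3448 in Slug (300 and 225) and 75 of 3287 in E47 (61 and 14).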

How the results depend on the processing

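The tests with label dyes, signs as deposited, turned transfectants, replicates by titled dye, the label dye as term, lists between transfectants and without the E47 1 array titled Cy3 were chosen after the results were seen; the others were planned. Counts are given for Snail, Slug and E47 against the control, then Snail against Slug, Snail against E47, Slug against E47 and the genes common to all 3, where they moved by more than 1.5 times. Median centring, either array as enough, all 6 replicates and robust moderation kept every count within that. The cause was not tested except where the setting itself uses fewer genes or arrays or a stricter limit. The arrays give no signal over background, so weak spots limit all values to an unknown degree, and with 2 replicates a lone replicate was assumed to vary like the other groups.

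Leaving out 1 replicate gave 34 to 345 genes for Snail, 339 to 891 for Slug, 26 to 275 for E47, 138 to 389 for Snail against Slug, 3 to 137 for Snail against E47, 8 to 27 for Slug against E47 and 10 to 45 common to all 3. Correlations ranged from 0.24 to 0.30 for Snail and Slug, 0.32 to 0.43 for Snail and E47 and 0.49 to 0.64 for Slug and E47. Lists past camera ranged from 1 to 4 in Snail, 3 to 7 in Slug and 3 to 11 in E47.

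Scaled to 1 spread, Slug had 440, Snail against Slug 271, Snail against E47 153 (30 higher and 123 lower) and Slug against E47 16. All 12 arrays with a dye term and the replicate as random effect gave 716, 1374, 593, 994, 493, 260 and 133; counted as independent they gave 605 for Snail, 509 for E47, then 840, 386, 185 and 117, and with the label dye as term 583, 447, 824, 362, 184 and 92. The last 2 count arrays of 1 sample as separate. Replicates formed by the titled dye gave 557 for Snail, 460 for E47, then 795, 329, 199 and 115.

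Arrays titled Cy5 alone gave 576 for Slug, 265 for Snail against Slug and 39 for Snail against E47, with a correlation of Slug and E47 of 0.51. Arrays titled Cy3 alone gave 56, 372, 42, 88, 1, 4 and 7, with a correlation of Snail and Slug of 0.23. Each probe on its own gave 572, 1964, 399, 1030, 240, 76 and 56, a correlation of Snail and E47 of 0.36 and 4 lists in Snail. Fits of only the groups compared gave 568, 539 and 391 against the control and 15 for Slug against E47. A 2-fold minimum gave 91, 207, 80, 228 for Snail against Slug and 14 common to all 3, and adjusted p under 0.01 gave 92, 329, 57, 73, 4, 1 and 13. Without the E47 1 array titled Cy3, E47 had 368, Snail against E47 199, Slug against E47 66, and 6 lists passed in E47.

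With signs by the label dyes and with signs as deposited, limma called 0 genes in each of the 6 comparisons and 0 common to all 3. At unadjusted p under 0.05, the label dyes gave 50, 209, 207, 79, 49 and 198 genes and the deposited signs 5, 44, 2, 15, 1 and 18. The correlations of Snail and Slug, Snail and E47, and Slug and E47 were 0.01, 0.15 and -0.08 with label dyes and -0.02, -0.04 and -0.22 as deposited. With Snail or Slug turned the first was -0.29, with Snail or E47 turned the second was -0.43, and with Slug or E47 turned the third was -0.62. Turning gave 357 genes for Snail against E47 and 985 for Slug against E47, and with Snail, Slug or E47 turned 4, 1 or 0 genes were common to all 3.

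A replicate block gave 294, 903, 231, 519, 101, 34 and 45, but the sample numbers did not pair samples across all transfectants. Deviations of the same number correlated with r of 0.02 for Snail and Slug and -0.06 for Slug and E47. For Snail and E47 r was 0.23, so a part common to samples of the same number stays open there. Lists past the test numbered 0, 0 and 0 with an estimated correlation, and fry passed 0 in Snail and 12 in Slug. Between transfectants, camera passed 1 list for Snail against Slug and 3 for Snail against E47, an estimated correlation 0 and 0, and fry 10 and 6. No list past camera reversed; among lists not past it, some did, such as proteases and endothelial markers in Slug with an estimated correlation. Among the named genes, PKM (-0.30) and EGFL7 (-0.20) changed direction in Slug with arrays titled Cy5. Of 270 results for named genes, 249 kept their direction and side of the threshold after scaling, 269 after centring, 270 with robust moderation and 144 with arrays titled Cy3; leaving out 1 replicate kept 195 (without Snail replicate 2) to 247 (without Slug replicate 2).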

Other observations

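No test was added for the values below, and EPCAM, COL15A1, GNG11, CDH2 and VIM, which the naming rule does not take, were chosen after their values were seen. EPCAM, an epithelial adhesion molecule, was far apart between replicates and did not pass in any transfectant: it had log2 ratios of -0.18 and -3.0 in Snail replicates 1 and 2 and of -0.36 and -2.69 in E47. It lay between -3.05 and -2.61 on the 5 turned arrays and between -2.59 and 0.15 on the 7 others. In Snail and Slug, sample and orientation coincide, so they cannot be told apart there. The E47 2 arrays, 1 of them turned, gave like values (-2.59 and -2.80). WNT5A, called in Slug, had 1.46 and 3.76 in Snail (adjusted p = 0.0512) and 0.90 and 3.53 in E47 (adjusted p = 0.0984). In Slug, CALD1 had 1.96 and -0.64, COL15A1, a basement membrane collagen, had 3.56 and 0.79 (adjusted p = 0.0234) and TCF4 had 3.15 and 1.08. In E47, ITGA5 had 0.53 and 2.69, CDKN1A had -0.34 and 1.74 and GNG11 had 0.51 and 3.14. Over all tested genes, replicates differed by more than 2 on the log2 scale for 3 genes in Snail, 10 in Slug and 5 in E47.

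Several standard markers of EMT did not pass: the log2 ratio of CDH2, N-cadherin, was 0.08 in Snail, 0.32 in Slug and 0.13 in E47, and that of VIM, vimentin, was -0.28 in E47 (adjusted p = 0.377), where both replicates were present only in that transfectant. Whether these probes for human genes read the dog transcripts was not tested, so a ratio near 0 need not mean an unchanged gene. The third CDH1 clone stayed near 0 (0.23 in Snail, -0.06 in Slug, 0.29 in E47) while the other clones fell. Among called genes with several clones, the clones had opposite signs for 4 of 35 genes in Snail, 11 of 93 in Slug and 1 of 33 in E47.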
